A study of Arabidopsis thaliana with 27 samples.

How the data were processed

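Chromatin immunoprecipitation and sequencing had been done on 14-day-old Arabidopsis thaliana seedlings with an antibody against GFP (lines expressing BRM-GFP or REF6-GFP) or against H3K27me3. Per the submitters' processing notes, reads were aligned to the TAIR10 genome with Bowtie2 2.2.5 and peaks were called with MACS 1.4. Each of the 17 lists used here belongs to 1 library. The input that served as control and the calling options are not given in the sources used here, and the 10 input samples were not analysed here. The lists give each peak's position and a score, which in the files deposited by the authors is −10 times the base-10 logarithm of the peak's p-value, with a minimum of 50 (p = 1e-05). Scores were used to describe, rank and filter peaks, as a log covariate in an alternative and, as the lower score of 2 libraries, to choose which genes to name. No difference in score between libraries was tested or read as a difference in binding. The lists carry no read depth, so the number of peaks and the covered length describe each library, and a peak missing from a list is not proof that the protein or mark was absent. Numbers of peaks ranged from 1466 (0.487 Mb) to 13079 (7.28 Mb).

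Genes were taken from the supplied gene table, 37887 nuclear loci on 5 chromosomes, of which 27432 are protein-coding. The table gives no strand. A gene was therefore called occupied when a peak overlapped its body or the 1000 bp on either side by at least 1 bp, where the plan had named the upstream side alone. These territories span 89.0% of the genome. The table belongs to TAIR10.1 and the peaks to TAIR10, so the peaks were shifted against the genes as a check: in 10 of 10 chromosome parts the overlap was best without a shift (59.3% to 64.7%, against 39.9% to 48.6% at a shift of 1000 bp). Coordinates in the text are those of the peaks, counted from 1. A test of the REF6 sequence motif was planned and was not run, because no genome sequence was at hand.

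A gene was called marked when H3K27me3 peaks covered at least 50% of its body. It was called gained when marked in both mutant libraries and in neither library of the other genotype, and lost in the reverse case. The same count was made for the other 2 ways of splitting the 4 libraries into pairs. REF6-GFP peaks of the 4 later libraries were merged into regions and compared in the same way. BRM-GFP peaks of the wild-type library were called lost when neither ref6 library overlapped them and kept when both did.

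Association was tested with Fisher's exact test, two-sided, over genes, peaks or regions, which are the units and not replicates. Overlap of REF6 and BRM peaks was set against 1000 random placements of the REF6 peaks, with their widths, within gene territories (permutation p, two-sided). The 7 tests of this plan formed 1 family for Benjamini-Hochberg adjustment at 0.05. Intervals are 95%, exact Clopper-Pearson for shares and conditional for odds ratios of Fisher's tests, and cover counting error only. Values are means ± SD over 2 libraries. Tests, thresholds and gene lists were fixed before the data were examined, except where the text says otherwise. The 12 lists of 106 genes covered floral identity, flowering time, meristem and boundary, auxin, seed maturation, gibberellin, brassinosteroid, phase change, light signalling, senescence, chromatin regulators and housekeeping, and 20 further families were defined by gene symbol. Each list and family was tested for 9 sets of protein-coding genes, 288 tests adjusted together.

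Genes named in the text are members of these lists and families, plus the 10 called genes, peaks or regions with the highest authors' score (the lower of 2 libraries) for each comparison and direction. A peak was named by the gene whose body it overlaps most, otherwise by the gene whose territory it overlaps.

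Alternatives were a score of at least 100, an overlap of at least 50% of the peak, territories of 3000 bp on either side, lists cut to equal length, the log score as covariate, any overlap or 80% of the gene as the mark's bound, no WT coverage, the replicate number as a block, and leaving out each library. Chosen after seeing the data were protein-coding genes only, the gene body only, strata of gene length, other REF6 lists, the share of sites marked and a background of genes that could be called. Whether replicate numbers pair libraries across genotypes was checked by correlating the within-group differences. The correlation was −0.0683 for WT and ref6, 0.0575 for WT and brm, 0.0330 for WT and brm ref6 and 0.286 for REF6-GFP in wild type and brm, and with 2 libraries per group the block was kept as an alternative only.

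Calling was tested with H3K27me3 in WT against simulated ref6 libraries, each of which kept 90% of 200 genes planted as gained. Of the 200, 85% were recovered, with 18 false gains among 37887 genes. Another split of the real WT and ref6 libraries gave 313 genes, so the 18 is not a false-call rate for these data. Random placements were called in 2.5% of 40 simulations. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.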

Results

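BRAHMA (BRM), the ATPase of a SWI/SNF chromatin-remodelling complex, and REF6, a Jumonji-domain demethylase of lysine 27 of histone H3, were mapped as GFP fusions in 14-day-old Arabidopsis thaliana seedlings by chromatin immunoprecipitation and sequencing. H3K27me3, the trimethylated form of that lysine, is deposited by Polycomb group proteins and marks silent genes. It was mapped in the same way with its own antibody. The 27 samples comprised 17 with a peak list (9 for GFP and 8 for H3K27me3) and 10 input samples, which were not used here. BRM-GFP and REF6-GFP were each represented by 1 library whose label named no further genotype, and these are called the first libraries. The later GFP libraries covered REF6-GFP in wild type and in the brm-1 mutant (2 libraries each) and BRM-GFP in wild type (1 library) and in the ref6-1 mutant (2 libraries). H3K27me3 was mapped in wild type (WT), brm-1, ref6-1 and the brm-1 ref6-1 double mutant, with 2 libraries each; the mutants are written brm, ref6 and brm ref6 from here on.

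The lists hold peaks and their scores, so the read depth behind them is unknown. The first BRM-GFP list had 12230 peaks over 8.23 Mb and the first REF6-GFP list had 5413 peaks over 6.81 Mb. The later lists were shorter, with 2209 to 4006 peaks for REF6-GFP and 1466 to 2564 for BRM-GFP. The H3K27me3 lists had 11132 to 13079 peaks, apart from ref6 replicate 2 with 5582 wider peaks (median width 1575 bp, against 289 to 527 bp in the other H3K27me3 lists). No peak was identical in both position and score between any pair of lists. The labels do not say that replicates came from separate plantings, so each test across libraries measures only the spread between these samples.

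The question for the first libraries was whether BRM and REF6 occupy the same genes. HB16, a homeobox transcription factor gene (AT4G40060), carried a peak of both proteins with the authors' score of 3100 in each list (BRM-GFP at chromosome 4, 18571290 to 18573503, and REF6-GFP at 18571099 to 18573692). Light-signalling regulators carried both proteins at 3 of 4 list members: PIF4 (BRM score 902, REF6 score 248), PIF5 (2744 and 98.7) and HY5 (324 and 715), while the photoreceptor gene PHYB had a BRM peak only. Among 8 brassinosteroid genes, 5 had a REF6 peak and 6 a BRM peak, with both at the transcription factor gene BZR1 (REF6 1504, BRM 649), the biosynthetic gene DWF4 (1012 and 308) and the cell-wall enzyme gene TCH4 (367 and 1149). The gibberellin list had BRM peaks at the DELLA genes RGA (1532) and GAI (683) and at all 3 GID1 receptor genes. REF6 peaks in that list lay at the biosynthetic genes GA20OX2 (3100) and GA20OX1 (1005), and no gene carried both. Senescence genes with both proteins were ORE1, NAP and EIN2, 3 of 5. Of the 10 shared loci with the highest lower score, 8 lay under a single peak at the start of chromosome 2 that includes the ribosomal RNA genes AT2G01010 and AT2G01020.

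Over 37887 nuclear loci, 9639 (25.4%) carried a REF6-GFP peak, 14416 (38.1%) a BRM-GFP peak and 5311 both. BRM occupied 55.1% of the REF6 loci and 32.2% of the other loci, an odds ratio of 2.58 (95% interval 2.46 to 2.71) by Fisher's exact test, whose two-sided p was too small to represent as a number (−log10 of the one-sided tail, 341). Of the 5413 REF6-GFP peaks, 2233 overlapped a BRM-GFP peak, which is 41.3% (exact binomial interval 39.9 to 42.6). The same peaks placed at random within gene territories overlapped one in 17.7% of cases on average and in 19.2% at most, a ratio of 2.33 (permutation p = 0.002, the smallest that 1000 placements can give; adjusted p = 0.0035 over the family of 7 tests). With BRM-GFP from the later wild-type library and REF6-GFP regions found in both later wild-type libraries, the odds ratio was 15.0 and the ratio to random placement 25.3. Of those REF6 regions 22.4% lay away from protein-coding territory, against 8.53% of those also in the first list, so background shared by the later libraries is not excluded as a source of the larger ratios. With an overlap of at least 50% of the peak the ratio was 3.63.

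BRM-GFP was compared between wild type and ref6 to ask whether BRM stays at its sites without REF6. The 10 highest-scoring wild-type BRM peaks that were absent from both ref6 libraries all overlapped a peak of the first REF6-GFP library. They lay at AT1G10220 (chromosome 1, 3352397 to 3353260, score 1064), the REF6 gene itself (chromosome 3, 17935085 to 17935806, score 883), AT5G59680, AT4G37235 and AT1G70550. Others lay within 1000 bp of the MADS-box gene AGL81 and at the heat-shock factor gene HSFA7A (chromosome 3, 19265251 to 19266097, score 621), AT2G42450, DIN9 and the auxin biosynthetic gene YUC3 (chromosome 1, 1280065 to 1280638, score 581). Peaks found in all 3 libraries included TCP8, a TCP transcription factor gene (chromosome 1, 21513618 to 21514427, score 1058), AT5G25280 (1160), AT5G56240 (1052) and AT1G35560 (871), none of which had a first-library REF6 peak. The highest-scoring kept peak, at AT2G08986 (3199) and without a first-library REF6 peak, lay at chromosome 2, 3617945 to 3626545. A REF6-GFP region found in all 4 later REF6-GFP libraries did lie there (3617927 to 3628186, score 2248). AT4G06700, AT5G31770 and AT1G40104, also among the kept peaks, had first-library REF6 peaks.

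Of the 1466 wild-type BRM peaks, 662 were in neither ref6 list, which is 45.2% (exact binomial interval 42.6 to 47.7), and 520 were in both. For comparison, 54.2% and 50.3% of the peaks of the ref6 libraries 1 and 2 overlapped a peak of the other ref6 library. Those shares are against 1 list, where the 662 were absent from both. Taken against 1 list, 43.6% of the wild-type BRM peaks overlapped ref6 library 1 and 46.7% overlapped ref6 library 2. The median score was 66.2 for the lost and 108 for the kept peaks. First-library REF6 peaks overlapped 41.8% of the wild-type BRM peaks (613 of 1466, 39.3 to 44.4). They overlapped 15.9% (399 of 2507, 14.5 to 17.4) and 18.5% (475 of 2564, 17.0 to 20.1) of those of the ref6 libraries. The first BRM-GFP library, whose label names no ref6 mutation, stood at 20.1% (19.4 to 20.9), close to the ref6 libraries, so this contrast rests on the single later wild-type library. Such shares also fall when a list gains peaks away from REF6. Of 2463 first-library BRM peaks at REF6, a fixed set, 17.9% overlapped a wild-type BRM peak, and 13.4% and 15.7% one of the ref6 libraries. Away from REF6 these shares were 5.29%, 6.97% and 8.22%. Against REF6 regions of both later libraries the shares of BRM peaks were 36.2% in wild type (531 of 1466) and 20.5% and 19.0% in ref6 (514 of 2507 and 488 of 2564). The counts at REF6 were close to each other there, so the lower shares in ref6 went with longer lists. Wild-type BRM peaks at first-library REF6 peaks were lost in 57.3% of cases (351 of 613), those away from them in 36.5% (311 of 853). Against REF6 regions found in both later wild-type libraries, as fixed before the data were examined, 48.4% of BRM peaks at REF6 (257 of 531) and 43.3% of the others (405 of 935) were lost. Among peaks either lost or kept in both ref6 libraries the odds ratio was 0.776 (0.610 to 0.986), with p = 0.0374 by Fisher's exact test and an adjusted p of 0.0523, which did not pass. This ratio leaves out peaks found in 1 of the ref6 lists and points the other way from the shares of all peaks, 48.4% and 43.3%. The direction also turned with the peak filter and the REF6 list. The odds ratio was 1.67 with scores of at least 100, 1.405 with the log score as covariate and 2.17 (1.70 to 2.77; Fisher's exact test, p = 1.18e-10) at first-library REF6 peaks. Without BRM-GFP ref6 replicate 1 it was 0.944. Wild type had 1 BRM-GFP library, so none of these differences has a replicate check on that side.

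**Figure D1:**
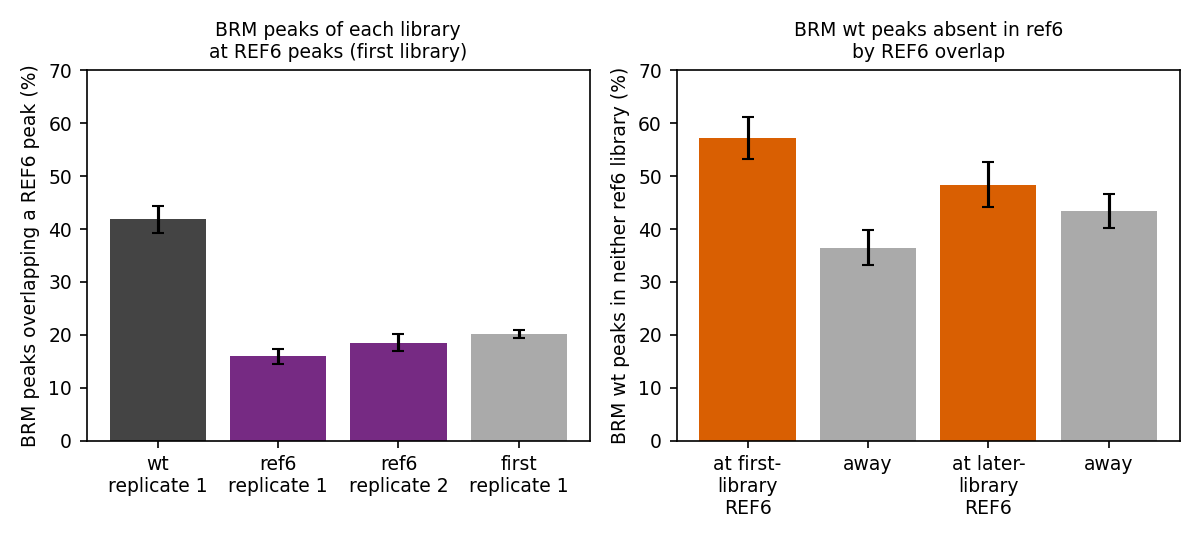
Left, the percentage of BRM-GFP peaks of each library that overlapped a peak of the first REF6-GFP library, 41.8% in wild type, 15.9% and 18.5% in ref6 and 20.1% in the first BRM-GFP library; right, the percentage of wild-type BRM peaks found in neither ref6 library, by overlap with first-library REF6 peaks (57.3% at and 36.5% away) or with REF6 regions of both later libraries (48.4% and 43.3%). The lists on the left differ in length, with 613 of 1466, 399 of 2507, 475 of 2564 and 2463 of 12230 peaks at REF6, in that order. Error bars are exact 95% binomial intervals and cover counting error only.

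In the opposite direction, 706 regions were present in both ref6 BRM lists and absent from the wild-type list. Of these, 29.9% overlapped a first-library BRM peak and 8.78% a first-library REF6 peak. Of the 10 with the highest score, 8 were intergenic, led by chromosome 4, 3984080 to 3987733 (score 1069) and chromosome 3, 14184963 to 14188118 (score 533), and the others lay at AT5G32293 and within 1000 bp of AT2G12690.

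REF6-GFP was compared between wild type and brm to ask whether REF6 needs BRM at its sites. Of 5186 merged REF6 regions in the 4 libraries, 1170 were present in all 4, 30 in both wild-type libraries and neither brm library, and 60 in both brm libraries and neither wild-type library. The lost regions had low scores: the highest were AT3G20362 (chromosome 3, 7103504 to 7104800, score 132), AT2G13115 (115), AT5G65660 (106) and, within 1000 bp, ELP (101). The gained ones were led by AT3G52330 (chromosome 3, 19405597 to 19406167, score 142), the sulfate transporter family gene SULTR3;4 (93.5), the laccase gene LAC3 (91.0) and NAKR1 (84.9). Regions kept in all 4 reached far higher scores. AT1G40104, AT4G06700 and AT2G01008, the last at the start of chromosome 2, stood at 3100, and AT4G37235 (2571), AT1G05700 (2353) and AGL81 (within 1000 bp, 2299) came lower. Of the 10 highest, AT1G40104, AT4G06700, AT5G31770 and AT2G08986 also held the highest-scoring BRM-GFP peaks kept in ref6. Background shared by the GFP libraries is therefore not excluded there. The mutant and wild-type lists differed by less than the replicates did: 969 regions were in both replicate 1 libraries and neither replicate 2 library, and 194 the other way round.

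First-library BRM peaks overlapped 7 of the 30 lost regions and 425 of the 1170 kept ones, an odds ratio of 0.534 (0.192 to 1.30) that did not pass Fisher's exact test (p = 0.178, adjusted p = 0.178). Each of the 4 libraries decided this result. The lost regions numbered 284 without REF6-GFP wild type replicate 1, 709 without wild type replicate 2, 428 without brm replicate 1 and 102 without brm replicate 2. The odds ratio then was 0.364, 0.229, 0.469 and 0.412, in that order, each past the threshold by Fisher's exact test (largest p = 0.000593).

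H3K27me3 in ref6 was set against WT to ask which genes gain the mark without the demethylase. CUC1 (AT3G15170), a NAC transcription factor gene of organ boundaries, had no H3K27me3 coverage in WT or brm and was covered over 99.2% ± 1.1 (SD, n = 2) of its length in ref6 (chromosome 3, 5109738 to 5111579 in replicate 1). It carried a REF6-GFP peak (score 594) and no BRM peak. The gibberellin biosynthetic gene GA20OX2 went from 0% in both WT libraries to 95.8% ± 5.9 (SD, n = 2) and the chlorophyll-degradation gene NYE2 from 0% to 94.4% ± 7.9 (SD, n = 2). YUC8, an auxin biosynthetic gene, rose from 32.3% ± 14.6 to 60.4% ± 13.6 (SD, n = 2 each). The gained genes with the highest scores were the neighbours AT5G56810 and AT5G56820 (lower score 1647 each), MDHAR (32.2% ± 9.7 to 87.1% ± 13.4), AT4G16745, the neighbours AT5G53720 and AT5G53730, PUB54 (0% to 91.0% ± 10.8), the alcohol dehydrogenase gene CAD3 (37.1% ± 12.99 to 98.5% ± 2.1), CYCB1;5 and SHV2. Of these 10, 6 carried a first-library REF6 peak and 1 a BRM peak. Among the genes that lost the mark, AT4G11030 fell from 68.3% ± 6.6 to 33.8% ± 15.7, the amino-acid transporter gene UMAMIT30 from 63.9% ± 12.5 to 30.04% ± 22.0 and CYP76G1 from 72.2% ± 5.1 to 32.2% ± 6.7 (SD, n = 2 each).

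With a gene called marked when peaks covered at least 50% of its length, 424 genes were marked in both ref6 libraries and neither WT library, and 141 the other way round. The other 2 ways of splitting these 4 libraries gave at most 313 genes, and 2 libraries against 2 cannot give a permutation p below 0.333. REF6 regions of both later wild-type libraries lay at 93 of the 424 gained genes (21.9%) and at 6.33% of the other genes unmarked in WT, an odds ratio of 4.16 (3.25 to 5.27; Fisher's exact test, p = 1.77e-25, adjusted p = 6.19e-25). With first-library REF6 genes, 64.4% of gained genes were occupied against 26.7% of the others. Counts of gained genes depended on the threshold and the library: 846 genes with any overlap, 171 with at least 80% of the gene, 256 with no WT coverage, and 1637 without ref6 replicate 1. In ref6 replicate 1, 2479 genes were marked, against 4965 in replicate 2, the library with the wide peaks.

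The share of REF6 peaks that carried H3K27me3, measured on the 5413 first-library peaks and chosen after the data were seen, was highest in the genotypes that lack REF6. It was 4.06% ± 0.25 in WT, 5.82% ± 0.73 in brm, 16.6% ± 1.4 in ref6 and 18.6% ± 3.0 in brm ref6 (SD, n = 2 each). REF6 peaks without a BRM peak stood at 4.73% ± 0.38 in WT and 20.8% ± 1.9 in ref6, and those with a BRM peak at 3.09% ± 0.06 and 10.6% ± 0.76 (SD, n = 2 each). BRM peaks without REF6 carried the mark in 2.75% ± 0.29 in WT, 3.01% ± 1.89 in ref6, 5.01% ± 0.20 in brm and 3.43% ± 0.77 in brm ref6 (SD, n = 2 each). Each ref6 and brm ref6 library lay above each WT library at REF6 peaks, and the exact permutation p of 0.333 is the smallest that n = 2 per group allows. REF6 peaks placed at random overlapped an H3K27me3 peak in 11.6% to 16.3% of cases across the 8 libraries.

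**Figure D2:**
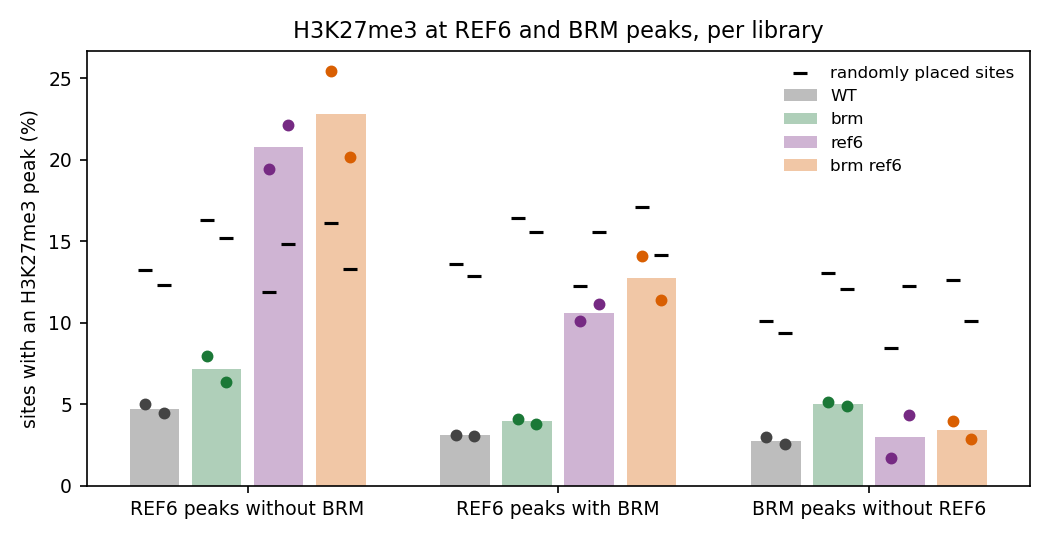
Percentage of REF6 peaks without BRM, REF6 peaks with BRM and BRM peaks without REF6 that overlapped an H3K27me3 peak, by genotype; bars are means of 2 libraries, points are single libraries and black dashes are the same sites placed at random. REF6 peaks without BRM stood at 4.73% in WT and 20.8% in ref6, while BRM peaks without REF6 lay between 2.75% and 5.01% in the 4 genotypes.

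H3K27me3 in brm was compared with WT to ask the same for BRM. MIR156C, a microRNA gene that keeps plants in the juvenile phase, was covered over 19.7% ± 19.7 in WT and 100% in both brm libraries, and it carried a BRM-GFP peak (chromosome 4, 15414910 to 15416251, score 1056) and a REF6-GFP peak (77.3). Both WT libraries already had an H3K27me3 peak on it (scores 605 and 407, against 190 and 283 in brm). The call there rests on how far the peaks reached, not on a peak absent from WT. IBH1, a regulator of brassinosteroid growth responses with a BRM peak (score 331), rose from 41.1% ± 11.8 to 78.2% ± 2.7, and the floral MADS-box gene SHP2 from 48.8% ± 1.3 to 61.8% ± 0.3 (SD, n = 2 each). The gained genes of highest score were AT5G13250 (49.1% ± 0.1 to 66.0% ± 2.0), AT5G03115, the ABC transporter gene ABCB16 (40.1% ± 10.1 to 72.4% ± 8.5), AT5G17950, AT3G31005, MIR169d, AT4G02925, AT4G26415, AT1G47370 and BETA-VPE, a vacuolar processing enzyme gene (37.8% ± 7.5 to 54.1% ± 0.4; SD, n = 2 each). Of these 10, 2 carried a BRM peak and 1 a REF6 peak. WRKY23, a transcription factor gene with a BRM peak (score 732), fell from 73.4% ± 3.5 in WT to 0% in both brm libraries, AT5G61120 from 92.5% ± 2.5 to 20.3% ± 10.8 and AT3G10575 from 73.2% ± 2.5 to 17.8% ± 2.4 (SD, n = 2 each).

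In brm, 508 genes gained the mark and 18 lost it, against at most 118 in the other splits of the 4 libraries. BRM occupied 120 of the gained genes (23.6%) and 40.5% of the other genes unmarked in WT, an odds ratio of 0.454 (0.366 to 0.559; Fisher's exact test, p = 1.73e-15, adjusted p = 4.03e-15). The genes gained in ref6 were BRM-occupied about as rarely, at 21.7% against 40.5% (odds ratio 0.407, 0.319 to 0.515), so a low share of BRM genes was not particular to brm. The 18 lost genes went the other way, with BRM at 10 of them and at 17.5% of the WT-marked genes that were not lost (odds ratio 5.91, 2.09 to 17.3, Fisher's exact test, p = 0.00031, chosen after the data were seen and not in the family). In ref6, too, BRM occupied more of the lost genes, 39 of 141 (27.7%) against 17.2% (odds ratio 1.84, 1.22 to 2.73, Fisher's exact test, p = 0.00302), so this was not particular to brm. With the brm lists trimmed by score to the covered length of the WT lists (7.40 Mb), chosen after the data were seen, 120 genes were gained and 176 lost. Equal covered length by itself works against an excess of gain over loss, so this turn does not show where the excess came from. The gained count was 99 with no WT coverage allowed, 924 without WT replicate 1 and 1087 without brm replicate 2.

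In the double mutant, the question was whether genes that both proteins occupy gain the mark. CUC1 was covered over 99.4% ± 0.9, GA20OX2 over 95.9% ± 5.8 and NYE2 over 78.6% ± 7.2, each from 0% in WT, and YUC3, with peaks of both proteins (REF6 score 3100, BRM score 115), over 56.3% ± 8.0 from 0% (SD, n = 2 each). YUC3 stood at 55.6% ± 8.9 (SD, n = 2) in ref6 as well, where 1 library at 49.3% kept it from being called. The highest-scoring gained genes were MDHAR (91.8% ± 3.1), CYCB1;5, AT3G58860, AT5G46000, the neighbours AT5G53710, AT5G53720 and AT5G53730, AT5G13250, and the glutathione transferase genes GSTF7 (0% to 94.8% ± 7.3) and GSTF6 (0% to 81.0% ± 1.9). Of these 10, 6 carried a REF6 peak and 2 a BRM peak. The mark was lost at the auxin transporter gene PIN2 (64.4% ± 15.4 to 44.4% ± 4.2), the nucleoside transporter gene ENT7 (61.3% ± 9.9 to 38.1% ± 15.2), NAC045, and the abscisic acid hydroxylase gene CYP707A4 (57.1% ± 3.7 to 31.9% ± 20.9). The highest score among lost loci was that of AT5G01675, a non-coding RNA locus that overlaps the floral repressor gene FLC. FLC itself stood at 95.9% ± 1.4 in WT, 95.8% ± 1.3 in brm, 89.4% ± 15.0 in ref6 and 41.8% ± 11.8 in brm ref6 (SD, n = 2 each), and was not called because 1 double-mutant library remained at 50.1%.

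In total 613 genes gained the mark and 218 lost it in brm ref6, against at most 187 in the other splits. Genes with both proteins made up 108 of the 613 (17.6%) and 15.2% of the other genes unmarked in WT, an odds ratio of 1.20 (0.961 to 1.48) that did not pass Fisher's exact test (p = 0.0996, adjusted p = 0.116). This value crossed 1 in both directions with the processing, from 0.721 with 80% of the gene covered to 1.93 with any overlap, while for REF6 genes of both later libraries, with or without BRM, it was 4.37. Against brm the double mutant gained 420 genes and lost 569 (at most 201 in the other splits). Against ref6 it gained 72 and lost 31, while another split of those 4 libraries gave 902, so no difference from ref6 could be read at the 50% bound. With any overlap it gained 405 and lost 69, against at most 265 in the other splits. BRM occupied 64 of the 218 lost genes (29.4%) and 16.8% of the WT-marked genes that were not lost (odds ratio 2.06, 1.49 to 2.83, Fisher's exact test, p = 1.16e-05, chosen after the data were seen), close to the 1.84 of ref6 alone. The gained count was 1395 without brm ref6 replicate 2.

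The gene lists fixed before the data were examined differed in their WT state. H3K27me3 covered at least 50% of the gene in both WT libraries at 12 of 14 floral identity genes, among them AG (98.9% ± 1.6), SEP3 (100%) and AP1 (99.0% ± 0.3; SD, n = 2 each). It did so at 9 of 13 meristem and boundary genes, among them STM (97.1% ± 0.6), WUS (100%) and CUC2 (100%), and at 3 of 5 seed maturation genes (LEC2, FUS3 and ABI3; SD, n = 2 each). All 6 housekeeping, 11 chromatin-regulator, 4 light-signalling, 8 gibberellin, 8 brassinosteroid and 5 senescence genes were unmarked in WT. Changes were few: of 14 floral identity genes SHP2 gained the mark, of 13 meristem and boundary genes CUC1, of 8 gibberellin genes GA20OX2, of 5 senescence genes NYE2, of 8 brassinosteroid genes IBH1 and of 5 phase-change genes MIR156C, with SHP2 and IBH1 called in both brm and brm ref6 (55.6% ± 2.8 and 61.8% ± 6.8 in brm ref6), CUC1, GA20OX2 and NYE2 in both ref6 and brm ref6, and MIR156C in brm (SD, n = 2 each). Among 14 auxin genes YUC8 was called gained in ref6 and YUC3 in brm ref6, and PIN2 lost in brm ref6. No seed maturation, light-signalling, chromatin-regulator or housekeeping gene was called. None of 13 flowering-time genes was called, although SOC1, a floral integrator gene with a BRM peak (score 465), stood at 51.9% ± 6.3 in WT, 11.1% ± 15.7 in ref6 and 0% in both double-mutant libraries (SD, n = 2 each). DWF4, not called either, stood at 0% in WT, 54.9% ± 10.3 in ref6 and 50.4% ± 2.0 in brm ref6 (SD, n = 2 each). None of 108 Fisher tests of these 12 lists passed after adjustment over all 288 list tests (lowest adjusted p = 0.232), and 5 had an unadjusted p below 0.05.

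Occupancy in the first libraries varied between these lists. Over all protein-coding genes the shares were 30.1% for REF6 and 44.1% for BRM. REF6 and BRM peaks, in that order, lay at 4 and 3 of 14 floral identity genes (AG, REF6 score 1225; PI, BRM score 796), 4 and 6 of 13 flowering-time genes (GI, BRM score 818), 4 and 2 of 13 meristem and boundary genes (CLV1, 208 and 780) and 5 and 6 of 14 auxin genes. They lay at 0 and 1 of 5 seed maturation genes (ABI5, 293), 2 and 4 of 5 phase-change genes (SPL9, 425 and 193), 2 and 5 of 11 chromatin regulators and 1 and 5 of 6 housekeeping genes, where UBQ10 had a BRM score of 1802.

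**Figure D3:**
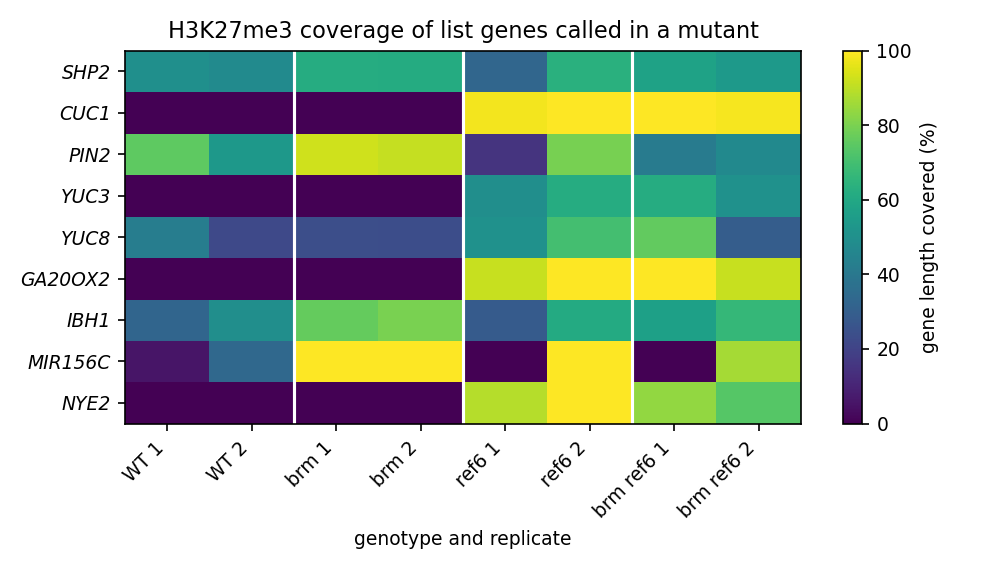
Percentage of gene length covered by H3K27me3 peaks in each of the 8 libraries for genes of the fixed lists called in at least 1 mutant. CUC1, GA20OX2 and NYE2 stood at 0% in WT and brm and above 70% in each ref6 and brm ref6 library.

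Families defined by gene symbol gave 8 calls. BRM occupied 19 of 23 ERF genes (odds ratio 6.03, 2.00 to 24.4, adjusted p = 0.0199) and 16 of 20 B-box genes (odds ratio 5.08, adjusted p = 0.0474), and 14 of 75 AGAMOUS-like MADS genes (odds ratio 0.290, 0.1498 to 0.525, adjusted p = 0.00173), by Fisher's exact test with Benjamini-Hochberg adjustment. NAC genes gained H3K27me3 in ref6 at 7 of 80 members (Fisher's exact test, odds ratio 7.42, adjusted p = 0.0119) and in brm ref6 at 7 of 80 (5.26, adjusted p = 0.0300). NAC080 and NAC027, which had peaks of both proteins, were covered over 82.5% ± 24.8 and 90.3% ± 13.7 in ref6, both from 0% in WT (SD, n = 2 each). AGAMOUS-like genes gained it in ref6 at 6 of 75 members (Fisher's exact test, odds ratio 6.71, adjusted p = 0.02501) and in brm ref6 at 7 of 75 (5.64, adjusted p = 0.02501). AGL89 rose from 0% to 93.9% ± 8.6 and AGL15, which had neither protein's peak, from 6.18% ± 8.73 to 91.3% ± 12.3 in ref6 (SD, n = 2 each). WRKY genes lost it in brm ref6 at 4 of 67 members, namely WRKY6, WRKY23, WRKY29 and WRKY57, which all carried a BRM peak (Fisher's exact test, odds ratio 10.3, adjusted p = 0.0346). With a background of genes that could have been called, the WRKY odds ratio was 2.56 (Fisher's exact test, adjusted p = 0.534) and the call was lost. The B-box result of Fisher's exact test was the same there, with an odds ratio of 5.08, and only the joint adjustment took it past the threshold (adjusted p = 0.0542). NAC003, NAC004 and NAC005 have nearby locus numbers, so members of a family are not independent.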

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

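Alternatives added after the results were seen are the other REF6 lists, gene body, gene length and protein-coding genes. Of 117 alternatives for the main results, 72 kept the result, 1 was weaker, 9 stronger, 10 reversed and 25 moved. For 74 coverage changes of named genes, 337 of 370 alternatives kept the value and 0 reversed. These genes were named because they were called, so leaving out 1 library could not reverse a change, and only the score filter could. Leaving out 1 library also could not move a change past the SD within which it counted as kept. Only the score filter therefore tested whether the value was kept, and the 337 of 370 is not a measure of stability. For the share of REF6 peaks marked, 7 of 12 alternatives kept the value, within the SD of the 2 libraries. Leaving out 1 of 2 libraries cannot move a mean past that SD, so only the score filter and the other REF6 regions tested it. At REF6 regions of both later libraries the share was 6.70% in WT, 7.67% in brm, 19.4% in ref6 and 22.1% in brm ref6. The cause of the shifts among the alternatives was not tested. The planned territory around the gene start and the motif alternatives were not run.

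BRM peaks lost in ref6 made up 41.3% with scores of at least 100, 50.7% with 50% overlap and 53.6% with equal list lengths, and 53.3% and 56.4% without BRM-GFP ref6 replicate 1 or 2. BRM loss at REF6 sites reversed to an odds ratio of 1.67 (scores of at least 100), 1.405 (log score), 2.17 (first REF6 library), 2.03 (later and first libraries) and 3.48 (first library with log score). Leaving out 1 library gave 0.628 to 0.944, and the highest value was without BRM-GFP ref6 replicate 1.

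REF6 regions lost in brm numbered 15 with scores of at least 100 and 758.5 on average within replicate numbers, with 755 gained. Without 1 library they numbered 284 (wild type replicate 1), 709 (wild type replicate 2), 428 (brm replicate 1) and 102 (brm replicate 2), and the odds ratio at BRM sites was 0.229 to 0.469.

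Genes gained in ref6 numbered 846 (any overlap), 171 (80% of the gene), 256 (no WT coverage), 1261.5 (block) and 441 to 1637 without 1 library, the highest without ref6 replicate 1. In brm they numbered 514 (any overlap), 99 (no WT coverage), 1177 (block) and 646 to 1087 without 1 library. The last range includes 924 without WT replicate 1 and 1087 without brm replicate 2. In brm ref6 they numbered 1184 (any overlap), 305 (80%), 358 (no WT coverage), 1175 (block) and 645 to 1395, the highest without brm ref6 replicate 2.

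Gain in brm ref6 at shared genes had an odds ratio of 0.955 (scores of at least 100), 1.20 (3000 bp), 1.93 (any overlap), 0.721 (80%), 1.74 (no WT coverage), 0.953 (block), 0.853 (gene body) and 1.27 (gene length). For a different set, REF6 genes of both later libraries with or without BRM, it was 4.37. Without 1 library it was 0.968 to 1.18, the lowest without WT replicate 1.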

Other observations

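The tagged genes themselves carried peaks. The widest peak of the first BRM-GFP library (10487 bp, chromosome 2, 18921421 to 18931907, score 2222) covered BRM, and the first REF6-GFP library had a peak over REF6 (chromosome 3, 17933287 to 17940641, score 1857). First-library BRM-GFP peaks also lay at other chromatin genes: the demethylase genes JMJ13 (score 703) and ELF6 (112) and the complex subunit gene SWI3C (66.2), while the SWI/SNF ATPase gene SYD had a REF6 peak (357). With BRM at 5 of the 11 listed chromatin regulators (45.5%), the share was near the 44.1% of all protein-coding genes.

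The patterns weighed below were chosen after the results were seen, and so were the tests of REF6-GFP chromatin, of partial WT coverage and of a WT or brm library.

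BRM loss in ref6 at REF6 sites went either way with the REF6 list. Background shared by the later GFP libraries is a candidate explanation: at REF6 regions that the first library also had, the odds ratio was 2.03 (1.56 to 2.66), and of 246 later regions found in both ref6 BRM lists and missing from the first REF6 list, 55.7% lay away from protein-coding territory, against 8.53% of 1208 shared ones. Weaker peaks being missed did not account for the loss at first-library REF6 peaks, since the odds ratio with the log score was 3.48 (2.65 to 4.58). REF6-GFP chromatin in the wild-type BRM library, as the source of all 351 such lost peaks, was argued against by the first BRM library. That library overlapped 71.8% (66.8 to 76.4) of them and 39.5% of REF6 peaks of like score without a wild-type BRM peak. The reference peaks were chosen to lack a wild-type BRM peak, which can itself lower their share. Such chromatin at part of the lost peaks is therefore not excluded. With 1 wild-type BRM library, the loss of BRM at REF6 sites stays a hypothesis.

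H3K27me3 gain in brm lay away from BRM genes. Genes crossing the 50% bound could be part of it, as 80.5% (76.8 to 83.9) of the 508 gained genes had some WT coverage, against 39.6% in ref6 and 41.6% in brm ref6. With any overlap, however, 514 genes without WT coverage were gained in brm and 34 lost, so the 50% bound was not the source of that count. BRM occupied 29.8% of these 514 and 41.4% of the other genes without WT coverage (odds ratio 0.601, 0.493 to 0.729). Spread from marked neighbours is a further candidate, since 70.7% of the 99 gained genes without WT coverage had a WT peak within 3000 bp, against 24.5% of other genes (odds ratio 7.46, 4.77 to 11.9), although ref6 (3.69) and brm ref6 (3.49) also exceeded 1. The longer covered length of the brm lists was left undecided: with the lists trimmed to 7.40 Mb, 120 genes were gained (99.5 to 143), against 111 in the highest other split of the trimmed lists (118 untrimmed), and 176 were lost. Trimming thus took the gained count from 508 to 120, near the other splits, and the lost count from 18 to 176. The excess of gain over loss did not outlast it, but equal covered length by itself works against such an excess. A true increase of the mark in brm would shrink as well, so the turn could not decide the question. By the rule written before the gained count was seen, a count above the other splits spoke against covered length. The interval, applied afterwards, spans both 111 and 118. Whether any gain beyond covered length remained was therefore left open.

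More genes were marked in ref6 replicate 2 than in replicate 1 (4965 against 2479). Wide peaks bridging gaps were not the whole cause: with gaps of up to 500 bp joined in replicate 1 the ratio was 1.73, against 2.00 before. A WT or brm library was argued against by the 17.6% (16.6 to 18.6) of REF6 peaks with the mark in replicate 2, where no WT or brm library exceeded 6.34%. A brm ref6 library was not tested and stays open: those libraries stood at 20.7% and 16.6%, on either side of replicate 2, and shared 63.8% and 53.2% of the joint covered length with it (ref6 replicate 1, 42.2%; brm, 58.5% and 55.9%), while single genes went both ways, WRKY23 (80.9% in replicate 2 and 72.7% in replicate 1, against 0% and 14.4% in brm ref6) with ref6 and AGL24 (100% and 0%, against 96.2% and 79.9%) with brm ref6. Different calling settings were not tested and could explain the minimum width of 394 bp, against 82 bp in replicate 1.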
